A study of Oryctolagus cuniculus with 9 samples.

How the data were processed

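The series holds mRNA sequencing of 9 libraries of the line HA-VSMC, in 3 groups of 3: control, β-estradiol at 50 nM and β-estradiol at 250 nM. Groups were taken from the sample titles. Per the labels' protocols, cells were grown in RPMI medium with fetal bovine serum, estradiol was dissolved in DMSO, cells were harvested after 48 h and RNA was isolated with TRIzol. The treatment protocol states 250 nM and no other concentration, and the control samples carry the tag estrogen for the treatment and WT for its concentration. The labels name a small RNA preparation kit for the mRNA libraries. The organism given is the rabbit, which was not checked, because reads were not used here.

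The authors deposited estimated counts and FPKM values per gene and library, made from trimmed and aligned reads. Per the submitters' processing notes, the tools were Trim Galore, TopHat2 2.1.1, Cufflinks and Cuffdiff; which of them made the count table, the genome build and the annotation are not given in the sources used here. The deposited counts are whole numbers, and their low values pile up at 4, 8 and 12. They were therefore treated as estimated counts in which about 4 units stand for 1 fragment, so that totals of 54718407 to 72274464 units correspond to about 13679602 to 18068616 fragments. The ratio of the deposited counts to the deposited FPKM values, relative to the same ratio in 1 library, varied between genes by at most 0.222% over 6088 genes. No rounding was needed. Libraries of the same group differed from each other by more than sampling noise (chi-square p of 8.15e-05 or lower), so none was merged with another as a repeat measurement. Separate preparations of 1 culture could differ in this way too. The columns of both tables were matched to samples by the group and number in their names, and 0 columns of other samples were left out.

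The table lists 19291 genes, 13318 by symbol and 5973 by an Ensembl identifier only. Of the symbols, 12501 matched a RefSeq gene table of the rabbit assembly mOryCun1.1, which was used for names only. Genes were kept by edgeR's filterByExpr (minimum count 10), which left 12324 genes, 9800 of them with a symbol, holding 99.99% of all counts. The counts do not state whether strand was used, so overlapping and antisense genes, and near-identical copies, could share counts.

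Differences were tested with edgeR 4.0.16 in R 4.3.3, by the quasi-likelihood test with TMM factors on all 9 libraries, which share an estimate of the spread. p-values were adjusted by the Benjamini-Hochberg method within each comparison, with a threshold of 0.05. The biological coefficient of variation was 8.92%. Comparisons were 50 nM with control, 250 nM with control, 250 nM with 50 nM, and an F test of any difference. Levels are CPM, computed here from the deposited counts with TMM factors.

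Gene lists, 32 in all, were fixed before the data were examined, from textbook knowledge. They cover Wnt targets and components, retinoid genes, estrogen response, steroid receptors and estrogen metabolism, smooth muscle, matrix and proteases, cell cycle and DNA replication, p53 and apoptosis. They also cover cholesterol, stress responses, hypoxia, interferon, inflammation, TGF-β, Notch and YAP/TAZ targets, immediate early genes, ribosomal and mitochondrial genes, and markers of endothelial, epithelial, leukocyte, fibroblast, and skeletal and cardiac muscle cells. Of 1110 different symbols, 805 were in the table and 703 were tested. The leukocyte and the skeletal and cardiac muscle lists had fewer than 5 genes tested and were not analysed. The other 30 were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01. Camera with a correlation estimated per list, and fry, which tests whether a list's genes move on balance in 1 direction, were run beside it.

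Named genes follow a rule that was also fixed before the data were examined. It takes STRA6, and the 10 largest rises and 10 largest falls among genes with a symbol that passed, had a mean of at least 5 CPM and did not overlap between the 2 groups. It adds up to 4 members of lowest p from each list that passed and from the Wnt, retinoid, estrogen response, steroid receptor and smooth muscle lists. Genes named outside the rule are said to have been chosen after their values were seen.

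Alternatives chosen before the data were examined were DESeq2 1.42.0, limma-voom, RLE and upper-quartile factors, no filter and a stricter filter (5 CPM in 3 libraries), only the 2 groups compared, and the replicate number as a block. Others were limma on log2(FPKM + 1) and log2(FPKM + 0.1) of the deposited FPKM values with and without a filter, a log2 fold change of at least 1, and leaving out each library. Counts divided by 4 were added after the data had been seen.

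The method was tested on simulated data with the libraries' own means, depths and spread, over 12333 genes of which 200 were changed. For 50 nM against control, 37.3%, 85.1% and 93.9% of genes changed by 1.25, 1.5 and 2 fold were recovered, and 10 of 154 calls were false. For 250 nM against control the shares were 31.3%, 74.6% and 95.5%, with 9 of 143 calls false. For 250 nM against 50 nM they were 31.3%, 80.6% and 87.9%, with 6 of 139 calls false. Changes of 1.25 fold were thus mostly missed at this depth and number of libraries. A simulated list of 30 genes raised by 1.25 fold was recovered by camera in each comparison, and 0 of 28 other lists was called. Genes were drawn independently in these simulations, so false list calls from correlated genes could not appear there. In the real libraries the estimated correlation was 0.48 for mitotic genes, against the preset 0.01. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.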

Results

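mRNA was sequenced from 9 libraries of HA-VSMC, a cultured cell line that the labels assign to the rabbit (Oryctolagus cuniculus). That species was not checked, and no other label gives the species or the tissue of origin of the line. Cells had been kept for 48 h with β-estradiol, the main estrogen of the ovary, at 50 nM in 3 libraries and at 250 nM in 3 libraries, and 3 libraries were controls. The series asks through which pathway estrogen takes part in adenomyosis, in which endometrial tissue grows within the muscular wall of the uterus. Its title names STRA6, the cell-surface receptor that takes up retinol, and the Wnt/β-catenin pathway. The labels do not state whether the controls received the vehicle. Nothing in them says that the replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

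The count table held 54718407 to 72274464 units per library, or about 13679602 to 18068616 fragments at roughly 4 units per fragment. Of its 19291 genes, 12324 had enough counts to be tested. FN1, which encodes the matrix protein fibronectin, took the largest share of each library, 5.85% to 7.25%. On the first principal component, which held 16.7% of the variance, the controls lay between -29.6 and -9.04. The 250 nM libraries lay between -2.85 and 3.14, and the 50 nM libraries between 13.7 and 19.1. On the second component, which held 14% of the variance, the 50 nM libraries spread from -19.6 (replicate 2) to 27.1 (replicate 3). There the controls lay between 0.512 and 12.5 and the 250 nM libraries between -11.2 and -9.14. Levels are given as CPM (counts scaled to the library total and its TMM factor), mean ± SD over 3 libraries, and log2 fold changes as estimate ± SE.

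The comparison of 50 nM estradiol with the control asked which genes responded to the lower concentration. EGR1 and FOS, transcription factors induced within minutes by growth factors and serum, had the largest falls among the genes named by the rule. EGR1 dropped from 305 ± 33.4 CPM to 41.6 ± 9.24 CPM, a 7.33-fold decrease (log2 fold change -2.87 ± 0.16, edgeR adjusted p = 3.93e-08). FOS dropped from 111 ± 14.0 CPM to 38.1 ± 3.55 CPM, a 2.92-fold decrease (log2 fold change -1.55 ± 0.10, edgeR adjusted p = 3.61e-07). TNFAIP3, an inhibitor of NF-κB signalling that NF-κB itself induces, rose 3.42-fold, from 24.6 ± 2.40 CPM to 83.9 ± 10.2 CPM. NFKBIA, which encodes the NF-κB inhibitor IκBα, rose 2.43-fold to 165 ± 5.01 CPM, and MAB21L3 rose 2.46-fold to 183 ± 4.99 CPM.

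SERPINB2, an inhibitor of plasminogen activators, rose by 1.22 ± 0.07 on the log2 scale. The aconitate decarboxylase gene ACOD1 rose by 1.12 ± 0.18, the endothelin gene EDN2 by 1.05 ± 0.14, and the Notch target HES1 by 0.95 ± 0.16. SDC4, a cell-surface heparan sulfate proteoglycan, rose by 0.92 ± 0.10, and the transcriptional repressors BHLHE40 and KLF10 by 0.86 ± 0.07 and 0.79 ± 0.07. Among the genes that fell, BTG2, an antiproliferative p53 target, changed by -0.89 ± 0.09. DUSP1 and DUSP6, phosphatases that switch off MAP kinases, changed by -0.87 ± 0.06 and -0.84 ± 0.10. The matricellular gene CYR61 changed by -0.73 ± 0.05 and SGO2, which protects centromeric cohesion, by -0.74 ± 0.09. LCA5, PPM1K and BCORL1 fell by 0.86 ± 0.11, 0.75 ± 0.13 and 0.71 ± 0.12. The edgeR adjusted p of each gene named since SERPINB2 was 0.00394 or lower. REL, which encodes an NF-κB subunit, was below the CPM minimum of the naming rule and was chosen after its values were seen; it rose by 1.56 ± 0.20 (edgeR adjusted p = 0.000418).

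**Figure D1:**
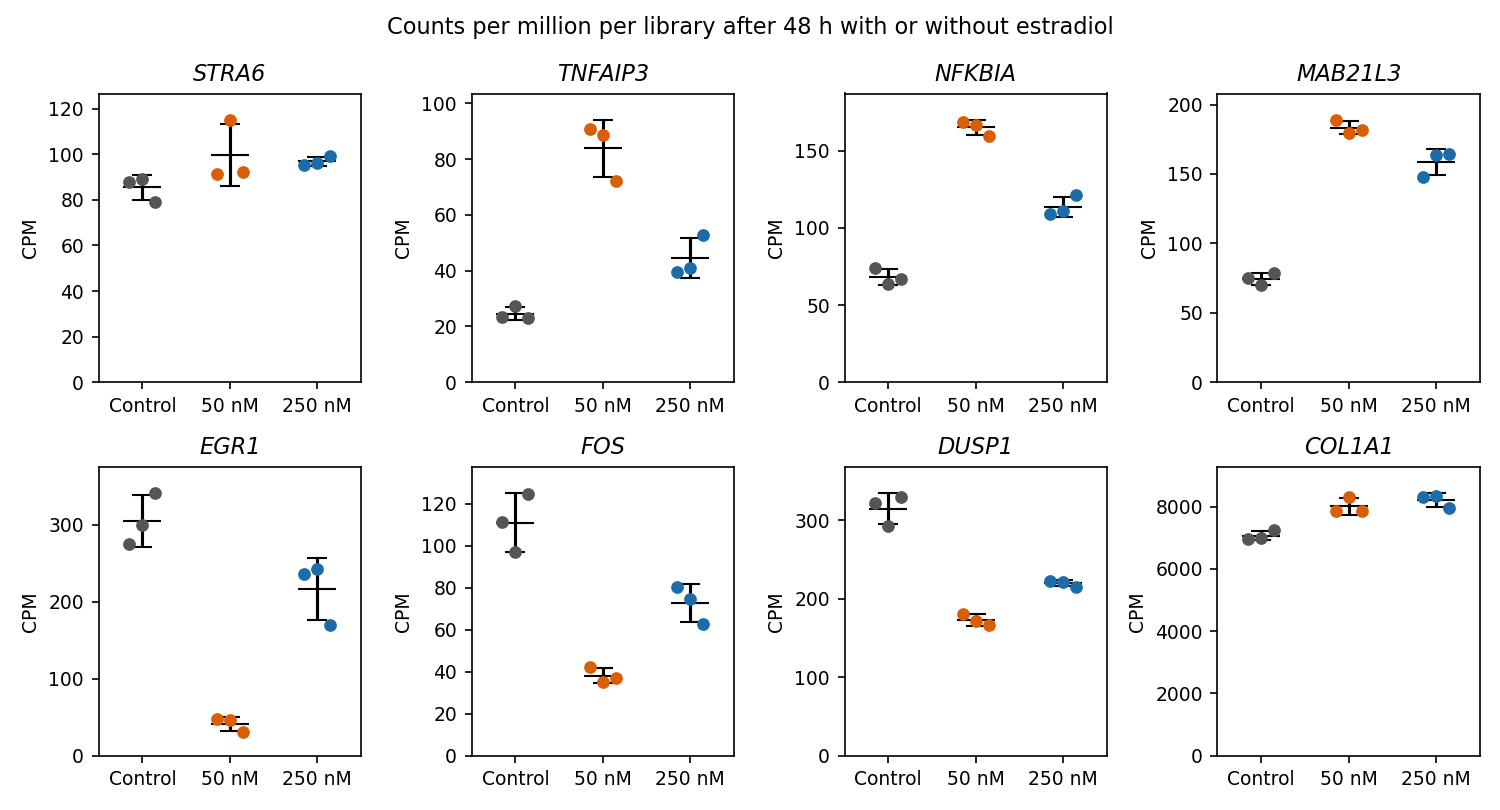
CPM in each library (points) for 8 genes, by group, with the mean (horizontal line) and SD (bars) over 3 libraries. EGR1 was 305 CPM in the control, 41.6 at 50 nM and 216 at 250 nM, TNFAIP3 was 24.6, 83.9 and 44.4 CPM, and STRA6 was 85.5, 99.6 and 96.9 CPM.

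In all, 401 genes changed at 50 nM, 191 higher and 210 lower (edgeR quasi-likelihood test, adjusted p under 0.05), with a median absolute log2 fold change of 0.41. Of these, 23 changed by at least 1 on the log2 scale, 16 upward and 7 downward, and 49 were known by an identifier only. The 3 libraries of each group did not overlap for 397 of them. Over all genes tested, 19.0% were separated in this way, against 10% by chance. Genes that pass the test are mostly separated for that reason alone, so separation adds no support to the calls, here or in the comparisons below. Which direction held more genes depended on the setting. On log2(FPKM + 1), where the median over all genes was -0.05, 98 were higher and 291 lower, while DESeq2 called 358 higher and 304 lower, and the fit with the replicate number as a block 258 and 234. More genes were also higher than lower without control replicate 2 (139 and 116) or 3 (98 and 89) and without 50 nM replicate 1 (108 and 105) or 3 (333 and 231). The count was 255 without control replicate 2, 187 without control replicate 3, 213 without 50 nM replicate 1 and 211 without 50 nM replicate 2.

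Of the gene lists fixed before the data were examined, inflammatory cytokines and NF-κB targets rose as a group at 50 nM, with a median log2 fold change of 0.25 over 26 genes (camera adjusted p = 3.93e-07, and adjusted p = 0.287 with an estimated correlation). Over all genes tested, 7 members rose and 0 fell; adjusted over the list alone, 13 rose and 1 fell. The 7 included CSF3, a granulocyte growth factor (0.77 ± 0.10), and the adhesion molecule ICAM1 (0.32 ± 0.05). Collagens and extracellular matrix genes rose as a list of 41 (median 0.15, camera adjusted p = 3.93e-07, and adjusted p = 0.287 with an estimated correlation): 3 members rose and 1 fell over all genes, and 19 rose and 1 fell adjusted over the list alone. THBS1, which encodes thrombospondin 1, rose by 0.50 ± 0.06, and the collagen I genes COL1A1 and COL1A2 each by 0.18 ± 0.04, while CYR61 fell. TGF-β targets and mesenchymal transition genes rose as a list of 30 (median 0.17, camera adjusted p = 2.51e-05, and adjusted p = 0.20 with an estimated correlation), with 6 members up and 0 down over all genes and 14 up and 1 down adjusted over the list alone. ID1 rose by 0.69 ± 0.12, ID2 by 0.60 ± 0.10 and TGFBI by 0.19 ± 0.04. Matrix proteases and inhibitors rose as a list of 36 (median 0.08, camera adjusted p = 0.00915, and adjusted p = 0.394 with an estimated correlation), with 2 members up over all genes, among them PLAU (0.34 ± 0.06), and 5 up adjusted over the list alone.

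Lists that fell at 50 nM included the immediate early genes, with a median of -0.18 over 24 genes (camera adjusted p = 0.0121, and adjusted p = 0.491 with an estimated correlation). In this list 10 members fell and 3 rose over all genes, and 11 fell and 6 rose adjusted over the list alone. The 3 that rose were KLF10, EGR3 and, chosen after its values were seen, the MAP kinase phosphatase gene DUSP4 (0.31 ± 0.06). Mitotic cell cycle genes fell as a list of 34 (median -0.14, camera adjusted p = 4.89e-08, and adjusted p = 0.473 with an estimated correlation), with 4 members down over all genes and 10 adjusted over the list alone. These 4 were ECT2, needed for cytokinesis (-0.41 ± 0.07), the kinesin CENPE (-0.40 ± 0.08), CDCA8 (-0.33 ± 0.07) and ASPM (-0.27 ± 0.06). Among 21 p53 target genes (median -0.18, camera adjusted p = 0.000465, and adjusted p = 0.0779 with an estimated correlation), 6 fell and 1 rose over all genes, and 8 fell and 2 rose adjusted over the list alone. CCNG2 changed by -0.51 ± 0.07 and the cell cycle inhibitor CDKN1A by -0.35 ± 0.05, while the kinase gene PLK3 rose by 0.54 ± 0.07. Cholesterol synthesis and uptake genes fell as a list of 25 (median -0.12, camera adjusted p = 0.000278, and adjusted p = 0.0779 with an estimated correlation), with 0 members past the threshold over all genes and 3 lower adjusted over the list alone. Heat shock genes fell as a list of 15 (median -0.11, camera adjusted p = 0.00139, and adjusted p = 0.20 with an estimated correlation), with 1 member down over all genes, the chaperone gene HSPA8 (-0.33 ± 0.04), and 3 adjusted over the list alone.

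STRA6 itself did not pass at 50 nM. Its level was 99.6 ± 13.5 CPM against 85.5 ± 5.54 CPM in the control. The log2 fold change was 0.22 ± 0.08, with a 95% interval of 0.05 to 0.40 (edgeR adjusted p = 0.181). Both ends of that interval, which is not adjusted for the number of genes, were positive. A small rise of STRA6 is therefore not excluded, and most of the smallest simulated changes were missed at this depth. None of the 24 retinoid genes tested, STRA6 among them, passed over all genes or adjusted over the list alone (camera adjusted p = 0.86). CYP26B1, which degrades retinoic acid, had a value of -0.42 ± 0.12 (edgeR adjusted p = 0.063). Of 15 Wnt/β-catenin target genes, MYC fell (-0.34 ± 0.07, edgeR adjusted p = 0.0108) and 0 rose; adjusted over the list alone, 3 rose and 3 fell (camera adjusted p = 0.945). Of 44 Wnt ligands, receptors and pathway components, WLS, which carries Wnt ligands to the cell surface, rose (0.21 ± 0.05, edgeR adjusted p = 0.0232) and 0 fell, in both adjustments (camera adjusted p = 0.555). Estrogen response genes had 2 of 27 members higher, in both adjustments: TIPARP (0.56 ± 0.08) and EGR3 (0.91 ± 0.20, at 2.49 ± 0.50 CPM against 1.32 ± 0.12 CPM). That list did not pass (camera adjusted p = 0.533), and its median of -0.01 had the opposite sign to its mean of 0.02. None of 19 steroid receptor and estrogen metabolism genes passed in either adjustment (camera adjusted p = 0.533). Of 25 smooth muscle contractile genes, MRTFA, a cofactor of serum response factor (0.27 ± 0.06), and PDLIM7 (0.31 ± 0.07) rose and 0 fell, in both adjustments (camera adjusted p = 0.124).

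At 50 nM 30 lists were tested, 9 passed camera with a preset correlation, and 0 passed with an estimated correlation, where 4 had an unadjusted p under 0.05. The fry test called 7. Of the 10 ways to divide the control and 50 nM libraries into 3 and 3, 3 passed at least 9 lists, the real one included. Without 50 nM replicate 3 the immediate early list no longer passed (camera adjusted p = 0.188), nor did the matrix protease list without control replicate 1 or 50 nM replicate 1 (0.0521 and 0.184). Among the genes named above, WLS, COL1A1, EGR3, PDLIM7, ASPM, CDCA8, MRTFA, COL1A2, CENPE, TGFBI and DUSP4 each lost the call without at least 1 library. The edgeR adjusted p of the lost calls was up to 0.0625, 0.0848 and 0.145 without control replicates 1, 2 and 3, and up to 0.0871, 0.11 and 0.0584 without 50 nM replicates 1, 2 and 3.

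**Figure D2:**
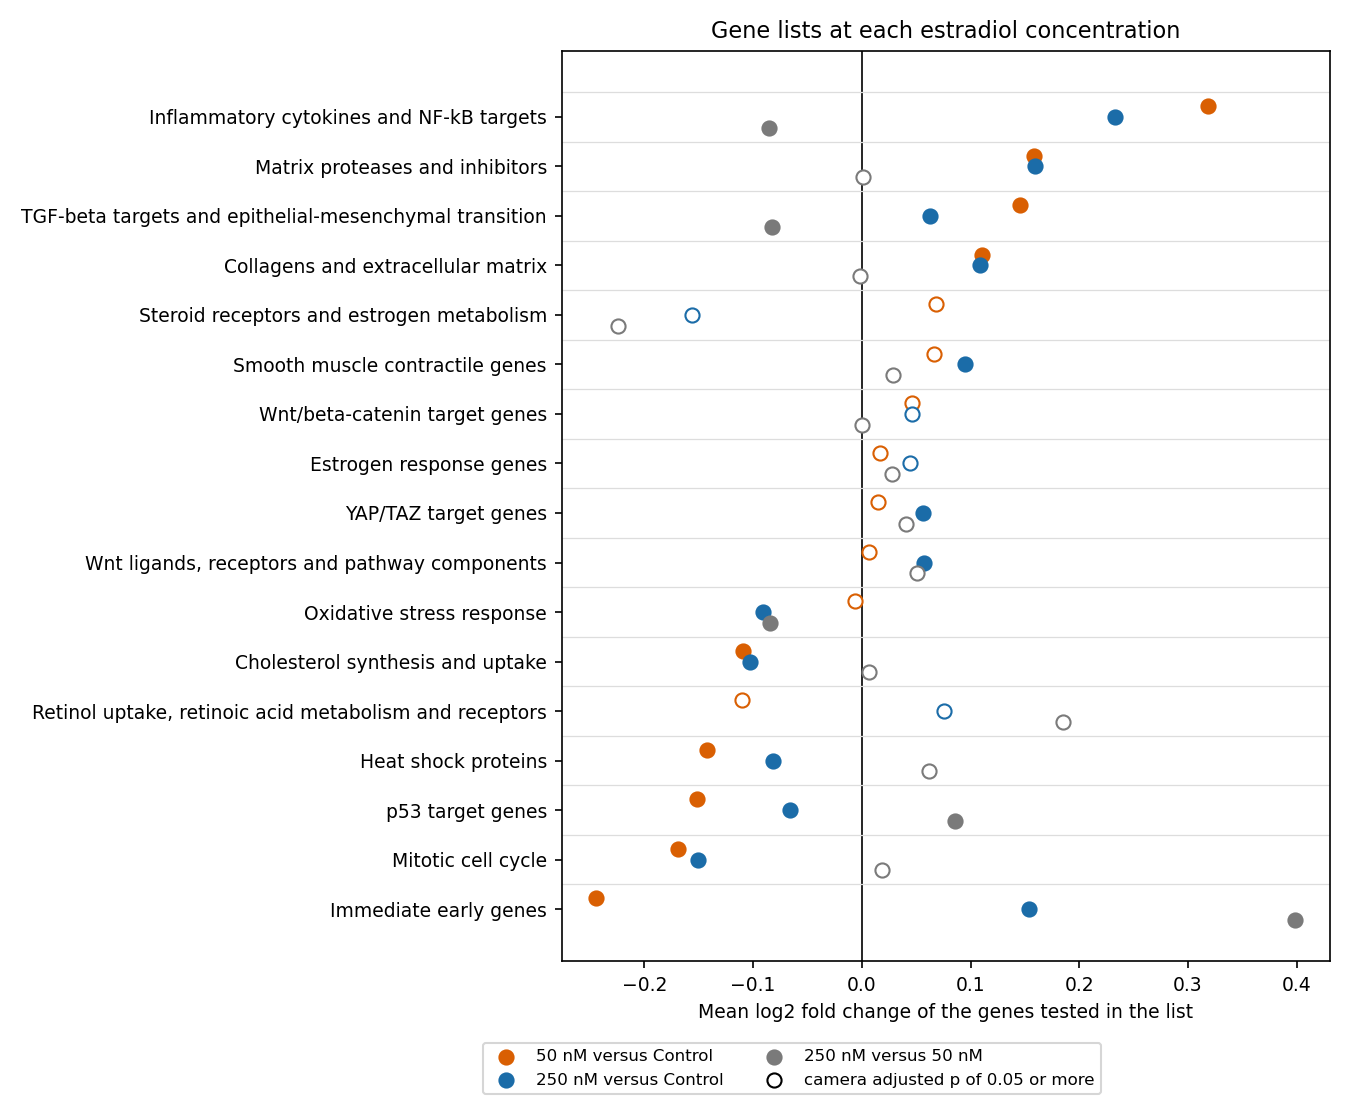
Mean log2 fold change of the genes tested in each of 17 lists (x axis), for 50 nM against control (orange), 250 nM against control (blue) and 250 nM against 50 nM (grey). Filled circles mark a camera adjusted p under 0.05 with the preset correlation; immediate early genes averaged -0.24, 0.15 and 0.40.

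The comparison of 250 nM estradiol with the control asked which genes responded to the higher concentration. MAB21L3 rose 2.13-fold, from 74.5 ± 4.22 CPM to 158 ± 9.44 CPM (log2 fold change 1.09 ± 0.06, edgeR adjusted p = 2.40e-07). TNFAIP3 rose 1.81-fold to 44.4 ± 7.18 CPM (0.86 ± 0.11, edgeR adjusted p = 0.00393), and NFKBIA 1.67-fold to 114 ± 6.53 CPM (0.74 ± 0.07, edgeR adjusted p = 6.48e-05). SERPINB2 rose by 0.71 ± 0.07 and SDC4 by 0.69 ± 0.10. IL6, which encodes the cytokine interleukin 6, rose 1.54-fold, from 17.4 ± 1.69 CPM to 26.7 ± 2.67 CPM (0.62 ± 0.11, edgeR adjusted p = 0.0227). The atypical IκB gene NFKBIZ rose by 0.60 ± 0.08, PLK3 by 0.53 ± 0.07, CSRNP1 by 0.49 ± 0.07 and the EGF-family ligand HBEGF by 0.49 ± 0.10.

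Lower at 250 nM were FOS (-0.61 ± 0.10, from 111 ± 14.0 CPM to 72.6 ± 9.05 CPM) and DUSP1 (-0.52 ± 0.06). HCFC2 changed by -0.48 ± 0.09, ZNF646 by -0.40 ± 0.08 and ZBTB11 by -0.39 ± 0.07. CCNG2 and CALHM2 each changed by -0.36 ± 0.07, the endothelin gene EDN1 by -0.35 ± 0.06 and CYR61 by -0.30 ± 0.05. EGR1, chosen here after its values were seen, had 216 ± 40.4 CPM against 305 ± 33.4 CPM in the control and did not pass (-0.50 ± 0.14, edgeR adjusted p = 0.231). Counted in full, 38 genes changed at 250 nM, 25 higher and 13 lower (edgeR quasi-likelihood test, adjusted p under 0.05), and the libraries of the groups did not overlap for all 38. Over all genes tested, 15.5% were separated, against 10% by chance. The 4 that changed by at least 1 on the log2 scale all rose: MAB21L3, EGR3 (1.16 ± 0.20), and, chosen after their values were seen, REL (1.08 ± 0.20) and ENSOCUG00000029235.1 (1.16 ± 0.19).

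STRA6 had 96.9 ± 2.14 CPM at 250 nM and did not pass (edgeR adjusted p = 0.554). Its log2 fold change was 0.18 ± 0.08, with an unadjusted 95% interval of 0.01 to 0.35. Both ends of this interval were positive too, so a small rise is not excluded here either. The interval rests on the same controls as that at 50 nM and is not independent of it. None of the 24 retinoid genes passed in either adjustment (camera adjusted p = 0.473). Of 15 Wnt/β-catenin targets 0 passed over all genes, and 1 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.731). The 44 Wnt ligands, receptors and components passed upward as a list (median 0.03, camera adjusted p = 0.0252, and adjusted p = 0.246 with an estimated correlation), with 0 members past the threshold in either adjustment. The 25 smooth muscle contractile genes also passed upward (median 0.10, camera adjusted p = 0.0159, and adjusted p = 0.302 with an estimated correlation), again with 0 members past the threshold in either adjustment. Among 27 estrogen response genes EGR3 rose and 0 fell, in both adjustments (camera adjusted p = 0.434). None of 19 steroid receptor and metabolism genes passed in either adjustment (camera adjusted p = 0.645), and their mean of -0.16 had the opposite sign to their median of 0.03 and to the test.

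Inflammatory and NF-κB target genes passed upward at 250 nM (median 0.15, camera adjusted p = 4.30e-07, and adjusted p = 0.246 with an estimated correlation), with TNFAIP3, NFKBIA and IL6 up and 0 down over all genes, and 6 up and 0 down adjusted over the list alone. Collagens and matrix genes passed upward (median 0.11, camera adjusted p = 4.22e-09, and adjusted p = 0.246 with an estimated correlation). Of these, THBS1 (0.32 ± 0.06) and COL1A1 (0.22 ± 0.04) rose and CYR61 fell over all genes, and 5 rose and 1 fell adjusted over the list alone. Matrix proteases passed upward (median 0.08, camera adjusted p = 0.00134, and adjusted p = 0.246 with an estimated correlation), with 0 members past the threshold over all genes and 2 up adjusted over the list alone. TGF-β targets passed upward (median 0.08, camera adjusted p = 0.0144, and adjusted p = 0.338 with an estimated correlation), with 0 members over all genes, and 5 up and 1 down adjusted over the list alone. The 22 YAP/TAZ targets passed upward (median 0.07, camera adjusted p = 0.0163, and adjusted p = 0.443 with an estimated correlation), although their member past the threshold over all genes, CYR61, fell; adjusted over the list alone, 2 rose and 1 fell. Immediate early genes passed upward (median 0.15, camera adjusted p = 0.0158, and adjusted p = 0.443 with an estimated correlation): DUSP4 (0.36 ± 0.06), EGR3 and, chosen after its values were seen, KLF10 (0.40 ± 0.07) rose and FOS and DUSP1 fell over all genes, and 8 rose and 4 fell adjusted over the list alone.

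Downward at 250 nM were mitotic genes (median -0.16, camera adjusted p = 1.09e-09, and adjusted p = 0.338 with an estimated correlation), with 0 members past the threshold over all genes and 7 lower adjusted over the list alone. Cholesterol genes also passed downward (median -0.11, camera adjusted p = 4.98e-05, and adjusted p = 0.0868 with an estimated correlation), with 0 members over all genes and 3 lower adjusted over the list alone. Among p53 targets (median -0.10, camera adjusted p = 0.0163, and adjusted p = 0.246 with an estimated correlation), PLK3 rose and CCNG2 fell over all genes, and 2 rose and 3 fell adjusted over the list alone. The 24 oxidative stress genes (median -0.06, camera adjusted p = 0.0163, and adjusted p = 0.574 with an estimated correlation) had 0 members past the threshold in either adjustment. Heat shock genes (median -0.05, camera adjusted p = 0.0158, and adjusted p = 0.246 with an estimated correlation) had 0 members over all genes and 1 lower adjusted over the list alone.

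At 250 nM 13 of the 30 lists passed camera, 0 passed with an estimated correlation, where 3 had an unadjusted p under 0.05, and fry called 2. The count of 38 genes was 21, 25 and 15 without control replicate 1, 2 and 3, and 25, 13 and 5 without 250 nM replicate 1, 2 and 3. MAB21L3, NFKBIA, SERPINB2, DUSP1 and TNFAIP3 kept their calls in all 9 runs that left out a library, and the other 25 of 30 passing genes followed through these runs lost theirs in at least 1. All 25 lost the call without 250 nM replicate 3 (edgeR adjusted p up to 0.26), 16, 13 and 18 without control replicates 1, 2 and 3 (up to 0.148, 0.184 and 0.189), and 16 and 19 without 250 nM replicates 1 and 2 (up to 0.214 and 0.239). Without 50 nM replicates 1 and 2, which enter through the shared spread, 7 and 1 did (up to 0.0796 and 0.0635). With the stricter filter, immediate early genes no longer passed (camera adjusted p = 0.132). Collagen, protease, mitotic, cholesterol and inflammatory lists passed in all 9 runs. The other 8 did not, with adjusted p up to 0.172 for Wnt components, 0.0971 for smooth muscle genes, 0.086 for p53 targets, 0.364 for oxidative stress genes, 0.0985 for TGF-β targets, 0.16 for YAP/TAZ targets, 0.113 for immediate early genes and 0.0621 for heat shock genes. The libraries whose removal ended these calls were control replicates 1 and 3 and the 3 libraries at 250 nM.

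Of the 38 genes, 34 had also changed at 50 nM, 22 higher and 12 lower at both concentrations. Independent lists of these sizes would share 0.387 and 0.222 genes, and simulated unchanged groups set against the same controls shared 0.02 in each direction on average. Those simulations held no changed genes, so a shared count near 0 was fixed in advance and cannot show what the shared controls add. The 4 others of the 38 genes were IL6, ERRFI1, a feedback inhibitor of the EGF receptor (0.43 ± 0.06), ENSOCUG00000022950.1 (0.52 ± 0.08) and ENSOCUG00000023997.1 (-0.60 ± 0.12). The last 3 were named after their values were seen. Over 12324 genes, which are not independent replicates, the log2 fold changes at the 2 concentrations correlated with r = 0.523, against 0.48 (0.40 to 0.548) in 50 simulations. Their covariance was 0.0533 against a simulated 0.0341, a difference of 0.0192. The 3 controls could not be divided into parts of at least 2 libraries, so part of the excess may come from the shared controls.

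**Figure D3:**
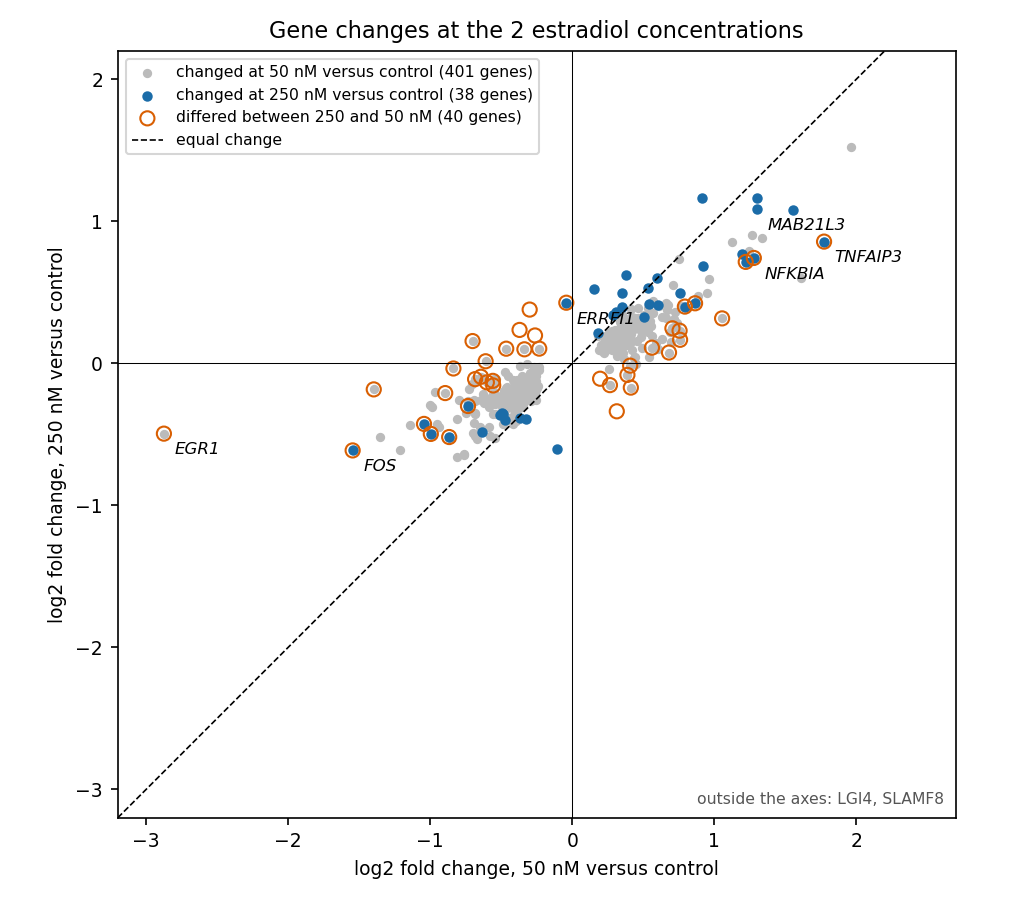
Log2 fold change against the control at 50 nM (x axis) and at 250 nM (y axis) for genes that changed in any of the 3 comparisons; circles mark the 40 genes that differed between the concentrations and the dashed line marks equal change. Grey points mark the 401 genes that changed at 50 nM and blue points the 38 that changed at 250 nM; LGI4 and SLAMF8, of low counts, lie outside the axes.

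The comparison of 250 nM with 50 nM tested the difference between the concentrations itself. EGR1 was 5.20-fold higher at 250 nM than at 50 nM, at 216 ± 40.4 CPM against 41.6 ± 9.24 CPM (log2 fold change 2.38 ± 0.15, edgeR adjusted p = 1.40e-06). FOS was 1.91-fold higher, at 72.6 ± 9.05 CPM against 38.1 ± 3.55 CPM (edgeR adjusted p = 0.000366). Also higher were the feedback inhibitors of receptor tyrosine kinase signalling SPRY2 (0.86 ± 0.12), SPRY1 (0.62 ± 0.10) and DUSP6 (0.80 ± 0.10). BTG2 and TRIB1 were each higher by 0.68, with SE 0.09 and 0.13. PTGS2, which encodes cyclooxygenase 2, was higher by 0.61 ± 0.10, and AHDC1 and FAM222A each by 0.57, with SE 0.06 and 0.11. ERRFI1, named after its values were seen, was higher by 0.47 ± 0.06. All of these passed (edgeR adjusted p of 0.0337 or lower).

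TNFAIP3 was 1.89-fold lower at 250 nM than at 50 nM (-0.92 ± 0.11, edgeR adjusted p = 0.000836). EDN2 was lower (-0.74 ± 0.14), as were the TGF-β pathway inhibitor SMAD7 (-0.65 ± 0.09) and the interferon regulatory factor IRF1 (-0.61 ± 0.06). The kinase genes CLK1 and NUAK2 had values of -0.59 ± 0.08 and -0.58 ± 0.06, and NFKBIA -0.54 ± 0.07. Hexokinase gene HK2 had a value of -0.53 ± 0.09, SERPINB2 -0.51 ± 0.07 and JMJD1C -0.46 ± 0.09. All of these passed (edgeR adjusted p of 0.0289 or lower). STRA6 differed by -0.04 ± 0.08, with a 95% interval of -0.21 to 0.13 (edgeR adjusted p = 1.0). Without 50 nM replicate 2 its value turned to 0.08, with an adjusted p of 0.934 in a range of 0.909 to 1.0 over the alternatives.

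Immediate early genes stood higher at 250 nM as a list (median 0.26, camera adjusted p = 5.72e-15, and adjusted p = 0.144 with an estimated correlation). Over all genes 9 members were higher and 1 was lower, and adjusted over the list alone 10 were higher and 1 was lower; IER3 was higher by 0.55 ± 0.06. The p53 targets passed upward (median 0.05, camera adjusted p = 0.0138, and adjusted p = 0.175 with an estimated correlation), with BTG2 higher over all genes and 3 higher and 0 lower adjusted over the list alone. Inflammatory genes passed downward (median -0.10, camera adjusted p = 0.0138, and adjusted p = 0.85 with an estimated correlation). In that list NFKBIA and TNFAIP3 were lower and PTGS2 was higher over all genes, and 4 were lower and 1 was higher adjusted over the list alone. TGF-β targets passed downward (median -0.05, camera adjusted p = 0.0138, and adjusted p = 0.702 with an estimated correlation), with SMAD7 lower over all genes and 4 lower and 0 higher adjusted over the list alone. Oxidative stress genes passed downward (median -0.05, camera adjusted p = 0.0138, and adjusted p = 0.85 with an estimated correlation), with 0 members over all genes and 1 lower adjusted over the list alone.

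Of the lists the study's question concerns, none passed between the concentrations. The Wnt/β-catenin targets (camera adjusted p = 0.913) had MYC higher at 250 nM (0.44 ± 0.07), and adjusted over the list alone 1 was higher and 1 lower; their median was -0.02 while the test pointed upward. The estrogen response genes (camera adjusted p = 0.923) had TIPARP lower (-0.45 ± 0.08), alone in both adjustments, and a median of 0.03 while the test pointed downward. Wnt components (0.268), retinoid genes (0.416), steroid receptor genes (0.913) and smooth muscle genes (0.913) had 0 members past the threshold in either adjustment.

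Between the concentrations 40 genes differed, 23 higher and 17 lower at 250 nM (edgeR quasi-likelihood test, adjusted p under 0.05). The libraries of the groups did not overlap for all 40, and over all genes 11.5% were separated, against 10% by chance. The 2 that differed by at least 1 on the log2 scale were EGR1 and, named after its values were seen, the receptor tyrosine kinase gene EPHA1 (1.21 ± 0.21). Of the 40 genes, 34 had changed at 50 nM against the control, all 34 with the opposite sign, against 0.04 on average in simulations of unchanged groups that shared the 50 nM libraries and 0.655 for independent lists. The low simulated count was fixed in advance, because no gene was changed there. The shared 50 nM libraries also favour opposite signs: the 2 sets of log2 fold changes correlated at -0.526 on average in the simulations. Leaving out 250 nM replicate 1 or 2 lowered the count to 23 or 21. The number of lists passing went from 5 to 2 without 50 nM replicate 1, 3 without 250 nM replicate 1 and 8 without 50 nM replicate 3. Of the 10 ways to divide the 50 nM and 250 nM libraries into 3 and 3, 5 passed at least 5 lists, the real one included. Immediate early genes and p53 targets passed in all 9 runs, while the inflammatory and TGF-β lists did not without 50 nM replicate 1 or 2 or 250 nM replicate 1 (adjusted p up to 0.244 and 0.156). The oxidative stress list did not pass without 50 nM replicate 1 or 3 or 250 nM replicate 3 (up to 0.334). Among the named genes, TRIB1, SPRY1, PTGS2, FAM222A, EDN2, HK2, JMJD1C, MYC, TIPARP and EPHA1 lost their calls without at least 1 library. Without 250 nM replicates 1, 2 and 3 there were 9, 10 and 5 such genes (edgeR adjusted p up to 0.236, 0.168 and 0.129). Without 50 nM replicates 1, 2 and 3 there were 5, 6 and 3 (up to 0.233, 0.144 and 0.0941), and without control replicate 3 there were 3 (up to 0.0591). The other 15 kept theirs in all 9 runs.

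A single test of any difference among the 3 groups called 229 of the 12324 genes (edgeR quasi-likelihood F test, adjusted p under 0.05), and 1481 had an unadjusted p under 0.05. EGR1, NFKBIA, MAB21L3, SERPINB2, TNFAIP3, DUSP1 and FOS were among the 229. The count was 122 without control replicate 3, 136 without 50 nM replicate 1 and 147 without 50 nM replicate 2.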

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

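The tests of a mixture, of selection and of growth state below were chosen after the results were seen. Those of the circadian clock and of ERK readouts were set before their genes were looked at. By the outcomes set then, both results would have counted against their explanations. Both are left open because each list had left out passing genes of its kind. That condition was not among the outcomes set.

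The change from the control differed between the concentrations for 40 genes (edgeR adjusted p under 0.05), which was singled out because the difference itself passed a test. Groups of 3 libraries were not tested for outlying samples.

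At 50 nM EGR1, FOS, DUSP6 and SPRY2, put together after their values were seen, were lower, while TNFAIP3 and NFKBIA were higher. Harvest at different phases of the circadian clock stays open: of 11 clock genes tested, 10 had a 95% interval within 0.5 of 0 (log2) and 0 passed, but this list left out BHLHE40 (0.86 ± 0.07) and PER1 (0.38 ± 0.07), which rose. Lower ERK signalling stays open too. Of 7 further ERK readout genes 0 fell and 3 rose adjusted over the list alone. These 3 were ETV5 (0.41 ± 0.08), SPRED1 (0.23 ± 0.09) and SPRED2 (0.19 ± 0.06). But the list left out EGR1, FOS, DUSP6, SPRY2 and SPRY1 (-0.61 ± 0.10), which all fell. Over all genes ETV5 also passed, but it lost that call without 50 nM replicate 2 (edgeR adjusted p = 0.0527). A different growth state of the cultures at harvest may account for the pattern and stays open, because mitotic genes had a median of -0.14 but did not pass with an estimated correlation (camera adjusted p = 0.473). Mitotic genes also had a median of -0.16 at 250 nM against the control. Between the concentrations their median was 0.02 (camera adjusted p = 0.593), while EGR1, FOS, DUSP6 and SPRY2 were higher at 250 nM. An effect of estradiol itself, the time since the last change of medium and the vehicle were not tested, since the labels give nothing that separates them from the groups.

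Changes looked smaller at 250 nM than at 50 nM: of the 401 genes changed at 50 nM, 388 had a smaller value at 250 nM, with a median ratio of the log2 fold changes of 0.534, against 0.744 over the 38 genes changed at 250 nM, and neither ratio was set against groups without a response. Libraries at 250 nM that held a mixture of control and 50 nM RNA are argued against, since at every mixing share at least 12 genes departed from the mixture (best share 0.51, chi-square 984 on 400 degrees of freedom, p = 4.18e-51). NUAK2 was among them, with 93.2 CPM in the control, 124 at 50 nM and 82.7 at 250 nM. This test covered only the 401 genes changed at 50 nM, and their selection by the same 50 nM and control values may enlarge the departures. The chi-square p also takes the genes as independent, although all were measured in the same libraries, so it may be far too small. Selection of genes by their 50 nM values may account for part of the pattern and cannot be told apart from a weaker response: of the 38 genes chosen at 250 nM, 25 changed more at 50 nM, 65.8% with an exact 95% interval of 48.6% to 80.4%. That interval takes genes from the same libraries as independent and may be too narrow. Choosing genes by their change at 250 nM may also enlarge that change. The direct comparison, which did not choose genes by their change at 50 nM, called the 40 genes above. It used the same 50 nM libraries, and 34 of its 40 genes had changed at 50 nM, so it is not independent of the 50 nM values. A culture or preparation that differed between the groups remains untested.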

How the results depend on the processing

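Counts divided by 4 is the alternative chosen after the data were seen. It gave 453, 41, 45 and 283 genes for 50 nM against control, 250 nM against control, 250 nM against 50 nM and any difference, with 9, 13 and 5 lists. Of 4773 values of the genes followed under the alternatives, 4310 kept their direction and their side of the threshold, 371 lost the call, 90 gained it and 2 reversed. Those were NR3C1 at 50 nM without 50 nM replicate 3 (0.00894, from -0.12, in a range of -0.20 to 0.00894, adjusted p = 0.976 in a range of 0.403 to 0.976) and STRA6 between the concentrations without 50 nM replicate 2 (0.0774). Neither passed in any setting, and the cause was not tested beyond the library left out. STRA6 did not pass under any alternative, with values of 0.10 to 0.28 at 50 nM, 0.13 to 0.21 at 250 nM and -0.10 to 0.08 between them. DESeq2 called 662, 128, 97 and 509 genes in the order above. On log2(FPKM + 1) without a filter the counts were 234, 4, 11 and 81, and for 250 nM against control 14 with a filter and 15 with a pseudocount of 0.1. Fitting the 2 groups alone gave 244 genes for 50 nM against control, 52 for 250 nM against control and 40 between the concentrations, and leaving out the filter gave 353 for any difference. A log2 fold change of at least 1 kept 23, 4 and 2 genes. Leaving out a library gave 187 to 564, 5 to 56, 21 to 50 and 122 to 339 genes, and 8 to 11, 9 to 15 and 2 to 8 lists. With an estimated correlation 0, 0 and 0 lists passed, and fry called 2 at 250 nM and 2 between the concentrations. The causes of these differences were not tested. No sign was seen that the replicate numbers pair the libraries: same-numbered libraries correlated at -0.03 to 0.04 in their deviations from the group means, and others at -0.08 to 0.07. With the replicate number as a block, 492, 43, 42 and 272 genes and 9, 13 and 5 lists passed. At this depth most of the smallest changes put into simulated data were not detectable (37.3% recovered for 50 nM against control).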

Other observations

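The genes in the first 2 paragraphs were chosen after their values were seen.

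At 50 nM some members of other lists passed although these lists did not pass at that concentration. Genes of the unfolded protein response fell: EIF2AK3, which encodes the stress sensor PERK, changed by -0.52 ± 0.08, the cochaperone DNAJB9 by -0.32 ± 0.08 and HERPUD1 by -0.25 ± 0.06, with 3 of 23 lower over all genes, and 3 lower and 1 higher adjusted over the list alone (camera adjusted p = 0.33). Among 24 interferon response genes IRF1 rose by 0.68 ± 0.06 and GBP1 by 0.36 ± 0.08, 2 genes in all and also 2 adjusted over the list alone (camera adjusted p = 0.691). Among 13 Notch genes HES1 and RBPJ, the DNA-binding partner of Notch, rose, RBPJ by 0.38 ± 0.08; adjusted over the list alone, 4 rose and 1 fell (camera adjusted p = 0.533). Of 29 hypoxia and glycolysis genes 1 rose, HK2 (0.76 ± 0.09), and 1 fell, and adjusted over the list alone 4 rose and 1 fell (camera adjusted p = 0.196). Of 24 oxidative stress genes 1 rose, HMOX1, which breaks down heme (0.37 ± 0.08), and 0 fell, and adjusted over the list alone 2 rose and 0 fell (camera adjusted p = 0.945). GBP1, RBPJ, DNAJB9, HERPUD1 and HMOX1 lost their calls without at least 1 library: the edgeR adjusted p was up to 0.109 for GBP1 and 0.112 for HMOX1 (control replicate 3 left out), 0.0692 for RBPJ and 0.102 for HERPUD1 (50 nM replicate 1) and 0.137 for DNAJB9 (control replicate 2). Control replicate 1 and 50 nM replicate 2 also ended some of these calls, and 50 nM replicate 3 and each 250 nM library ended that of DNAJB9 (up to 0.0771). IRF1, EIF2AK3 and HK2 kept theirs in all 9 runs.

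Receptors for estrogen had low counts. In the control, ESR1 had 1.59 ± 0.46 CPM and ESR2 0.78 ± 0.19 CPM, and GPER1, with 0 to 15 table units per library, was not tested. The progesterone receptor gene PGR, an estrogen target in the uterus, had 12.2 ± 0.75 CPM in the control, 11.3 ± 0.98 CPM at 50 nM and 11.8 ± 1.22 CPM at 250 nM, and did not pass (edgeR adjusted p = 0.706 and 0.96). ACTA2, the actin of smooth muscle and myofibroblasts, had 3012 ± 89.3 CPM in the control, 3018 ± 184 CPM at 50 nM and 2949 ± 111 CPM at 250 nM, and did not pass. CTNNB1, which encodes β-catenin, had 820 ± 30.6 CPM in the control and the Wnt target AXIN2 8.02 ± 0.80 CPM, and neither passed in any comparison.

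Of the 30 lists tested, 17 passed in no comparison. Besides the Wnt/β-catenin target, retinoid, estrogen response and steroid receptor lists, these were DNA replication (lowest camera adjusted p 0.0795), hypoxia and glycolysis (0.0992), unfolded protein response (0.234), interferon response (0.321), Notch (0.473), nuclear oxidative phosphorylation genes (0.473) and apoptosis regulators (0.545). Mitochondrially encoded genes (0.555), amino acid stress (0.659), cytosolic ribosomal proteins (0.681), and endothelial (0.473), epithelial (0.252) and fibroblast markers (0.645) did not pass either.

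Other splits of the libraries were fitted in the same way. For any difference among the 3 groups, the real grouping gave 229 genes and the highest of the other splits 121. Of 100 splits drawn from the 280 possible, 1%, the real one, reached the count. This argues against a chance division of these libraries but does not exclude it. The other splits mix groups that may differ, which widens their spread and can lower their counts. The split with 121 genes kept the 3 controls together and exchanged replicate 3 between the 50 nM and 250 nM groups. It therefore held part of any real difference, which can raise its count. With 3 libraries against 3 there were 10 splits, too few for a share under 0.05. The real counts were 401, 38 and 40 genes and the highest others 1, 1 and 2. The real list counts were 9, 13 and 5 and the highest others 13, 7 and 9. At least as many lists passed in 3, 1 and 5 of the 10 splits, the real one included. The list counts at 50 nM and between the concentrations were thus also reached by wrong groupings.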
